A study of Mus musculus with 78 samples.

How the data were processed

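The series holds 78 libraries from mouse cells, of which 60 were made from 1 cell each and 18 from pooled cells, embryos, pronuclei or sperm DNA. Most are MAB-seq libraries. In MAB-seq the CpG methyltransferase M.SssI first methylates every unmodified CpG, after which bisulfite converts only 5-formylcytosine (5fC) and 5-carboxylcytosine (5caC) at CpG, the products that TET enzymes make on the way to active demethylation. A T read at a CpG therefore marks 5fC or 5caC, a CpG that M.SssI missed, or a C-to-T difference between the cells and the reference. In bisulfite sequencing (BS-seq) a C read marks 5-methylcytosine or 5-hydroxymethylcytosine. Per the labels' protocols, the libraries followed either reduced representation bisulfite sequencing (RRBS, which reads CpG-rich restriction fragments) or post-bisulfite adaptor tagging (PBAT, which reads the whole genome). RRBS and PBAT libraries were never mixed in a comparison.

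Reads were trimmed with Trim Galore and processed with Bismark, and the build was mm9, per the submitters' processing notes, and the versions are not given in the sources used here. Whether PCR copies were removed is not given in the sources used here either. The deposited files list CpG cytosines of each strand separately, in 8 columns without a header, 1 library per file. The deposited counts are whole numbers of C reads, T reads and total reads per cytosine, and C and T reads add up to the total in every line. The deposited percent at each cytosine equals the T share in MAB-seq files and the C share in BS-seq files, which was tested on every line. Reads off chromosomes 1 to 19, X and Y made up 0.186% to 38.7% of a library and were left out. No annotation of mm9 was used here, so windows are named by chromosome and mm9 position only, and the gene lists fixed for the case of an mm9 annotation were not tested.

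The level of a library is the mean over its covered CpG cytosines of the T share (MAB-seq) or the C share (BS-seq), in percent, with each cytosine counted once so that PCR copies of one fragment weigh little. Windows of 1000 bp were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, C and T counts of each library, a term for each library and a group term on the C to T odds). A window was tested with at least 10 reads and 3 CpG cytosines in every library of the comparison, on chromosomes 1 to 19 and X. It was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 5 percentage points (MAB-seq) or 10 percentage points (BS-seq). Windows were classed by the number of distinct CpG dinucleotides seen over all files (under 20, 20 to 59, 60 or more) and, for zygotes and sperm, by the sperm BS level (under 20%, 20 to 80%, over 80%). The 5 windows with the lowest p in each direction, at least 1 Mb apart, are named.

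The strand index of a chromosome in a cell is (W − C)/(W + C), where W and C are the shares of covered CpG cytosines of the plus and minus strand whose T share is at least 0.25. The strand bias of a cell is the square root of the mean, over the 19 autosomes, of the squared index minus its binomial sampling variance, set to 0 where negative. Strand switches were placed by binary segmentation in bins of 1 Mb, with a log-likelihood gain of at least 12, at least 5 Mb on each side and a binomial z of at least 4 of opposite sign on the sides. Blastomeres whose titles share a number were taken as cells of 1 embryo, and embryo means were the units of tests between stages. Exact permutation tests listed every split, and re-pairing of sister cells used all 40320 pairings of 8 and 8 cells. Permutation tests are two-sided, except the shuffling tests of 4-cell embryos, which count in a single direction. Wilson intervals at 95% are given for shares of reads in single libraries and cover counting error only, since reads are not independent molecules.

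The groups, tests, coverage minimums, window sizes, thresholds, classes, naming rule and 69 alternatives were fixed before the data were examined, and 19 alternatives were added afterwards. Several choices came later. edgeR's usual estimate of a negative binomial dispersion recovered none of the windows changed in simulated data, so the dispersion was set to 0 and the spread between libraries left to the quasi-dispersion, and the counts under the usual estimate are given beside the results. Single RRBS cells fell into separate sets by the share of cytosines with at least 20 reads whose T share lay above 0 and under 10%, a sign of scattered T reads at well-covered cytosines. This share was at most 7.81% in one set and at least 22.4% in the other, and the dividing value of 15% was set after it was seen. Values are also given within these sets, called low-noise and high-noise cells. Also set later were the exclusion of cytosines with at least 10 reads and a T share of 80% or more, the minimum of 5 reads for single RRBS cells at called windows, the division of embryos by X coverage at 3.5% of the autosomal cytosines, and an index of 0.25 for calling a chromosome biased. The test of switch events against chromosome length was not fixed beforehand either.

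No culture is named for the single embryonic stem cells (ESCs), so the cells of a line are measurements of 1 sample. Permutation tests between single cells had been fixed for these lines and were computed, and they were then left out of the text. Means, SDs and ranges over cells stand in their place, also where blastomeres are set beside ESCs. The labels do not say whether numbered pooled libraries came from separate cultures, males or collections of zygotes, so adjusted p-values measure only the spread between these libraries, which may be technical. Window levels of numbered libraries correlated at Pearson's r of 0.158 to 0.968. This does not tell whether they are technical copies, since read sampling alone lowers r. In MAB-seq r was 0.207 between the shTdg, 0.158 between the Tet TKO and 0.315 between the Dnmt TKO libraries. It was 0.357 between the pronuclear and 0.163 between the sperm MAB-seq libraries, so T levels of single windows were weakly reproduced.

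The window test was tested on simulated data with the read numbers of the real windows. In each comparison 200 windows of low mean level were changed by adding 10, 30 or 60 percentage points of T (MAB-seq) or C (BS-seq). Losses were not simulated, so how well the test recovers lower windows, the greater part of the BS calls, was not tested. For shTdg against Tet TKO (92309 windows) the test recovered 0%, 45.7% and 90% of the changed windows, and 4 of 99 calls were false. For Dnmt TKO against Tet TKO (70185 windows) it recovered 3.3%, 60% and 95.7%, and 11 of 122 calls were false. For pronuclei against sperm it recovered 0%, 22.9% and 85.7% in MAB-seq (77541 windows) with 37 of 113 calls false, and 6.7%, 27.1% and 77.1% in BS-seq (77426 windows) with 52 of 129 calls false. False calls thus exceeded the 5% that the adjustment aims at in 3 of the 4 comparisons when few windows had changed. Segmentation of simulated 2-cell blastomeres made 0 false switches and recovered 90.1% of true ones in low-noise and 59.1% in high-noise cells, and of those simulated in single RRBS ESCs it recovered 0.957% in shTdg and 0% in Tet TKO cells, a simulation added after the results were seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.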

Results

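Active DNA demethylation was followed in mouse ESCs, sperm, zygotic paternal pronuclei and blastomeres of 2-cell and 4-cell embryos. The single-cell MAB-seq libraries comprised 26 blastomeres of 18 wild-type 2-cell embryos, 8 blastomeres of 2 4-cell embryos, 11 ESCs with a Tdg knockdown (shTdg) and 4 Tet TKO ESCs by RRBS. By PBAT they comprised 4 blastomeres of 1 4-cell embryo, 4 shTdg ESCs and 3 Tet TKO ESCs. TDG is the glycosylase that removes 5fC and 5caC, and Tet TKO cells lack the enzymes that make them, so Tet TKO libraries give the background of the assay. Pooled RRBS MAB-seq libraries were made from shTdg, Tet TKO and Dnmt TKO ESCs (2 each), from 2-cell embryos (1), from paternal pronuclei (2) and from sperm (2), with BS-seq of pronuclei (2) and sperm (2). All were low-input libraries except those of sperm, which are titled regular. A library of shTdg ESCs by regular MAB-seq (1) and PBAT pools of shTdg and Tet TKO ESCs (1 each) completed the set. In units of 1000 CpG cytosines, a 2-cell blastomere covered 93.4 to 192.6 with 6051976 to 20261035 reads, a 4-cell RRBS blastomere 98.1 to 210.3 with 985268 to 6296995 reads, and a single RRBS ESC 151.1 to 480.2 with 6663231 to 29030333 reads. Single PBAT cells covered 1374.1 to 6086.4 with a median of 1 read per cytosine. Pooled RRBS libraries covered 966.1 to 2031.0 with 20616184 to 38476712 reads.

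The first question was whether single ESCs with less TDG to excise 5fC and 5caC carry more T than cells that cannot make them. By PBAT, the T level was 5.0% ± 0.560 (SD, n = 4 cells) in shTdg ESCs and 2.60% ± 0.0656 (SD, n = 3 cells) in Tet TKO ESCs, and the lowest shTdg cell (4.35%) lay above the highest Tet TKO cell (2.64%). By RRBS the levels were 7.23% ± 2.10 (SD, n = 11 cells) and 6.24% ± 2.39 (SD, n = 4 cells), and the ranges of 3.70% to 9.86% and 3.32% to 9.17% overlapped. The difference of 0.995 percentage points between the RRBS lines was smaller than the spread between cells and was 0.0224 points without Tet TKO replicate 3. Low-noise and high-noise cells stood apart within both lines. Among low-noise cells the level was 6.26% ± 1.53 (SD, n = 8) in shTdg and 3.32% in the only Tet TKO cell, and among high-noise cells 9.82% ± 0.0391 (SD, n = 3) and 7.21% ± 1.71 (SD, n = 3). With at least 5 reads per cytosine the lines stood at 5.56% ± 1.59 and 3.94% ± 1.29. The cells of each line are 1 sample, so no p-value is given.

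Blastomeres of 2-cell embryos carried 10.7% T ± 2.48 (SD, n = 18 embryos), against 6.24% in the Tet TKO ESCs, which are the background at hand but another cell type. The levels were 8.32% ± 0.633 (SD, n = 7 embryos) against 3.32% in low-noise cells, and 12.3% ± 1.87 (SD, n = 11 embryos) against 7.21% ± 1.71 in high-noise cells. With at least 5 reads per cytosine the 2-cell embryos stood at 8.24% ± 1.35 and the Tet TKO ESCs at 3.94% ± 1.29. Cytosines with under 5 reads held more T than those with at least 20 in both groups, 17.3% against 7.79% in blastomeres. Levels over all cytosines thus depended on coverage. Pooled libraries were lower, at 6.37% in 2-cell embryos (n = 1) and 2.87% ± 0.0814 in Tet TKO ESCs (n = 2). The 2 4-cell embryos measured by RRBS, whose cells were all high-noise, stood at 8.70% ± 1.20. The difference of 2.03 points between the stages did not pass an exact permutation test (p = 0.358, n = 18 and 2 embryos, smallest possible p 0.0105). It was 0.0968 points on pooled reads and 0.351 points with at least 5 reads per cytosine, 1.18 points without 4-cell embryo 1 and 2.88 points without embryo 3. Among high-noise cells, the set that holds every 4-cell blastomere, it was 3.57 points (exact permutation p = 0.0513, n = 11 and 2 embryos), and 1.12 points there with at least 5 reads per cytosine (exact permutation p = 0.205).

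**Figure D1:**
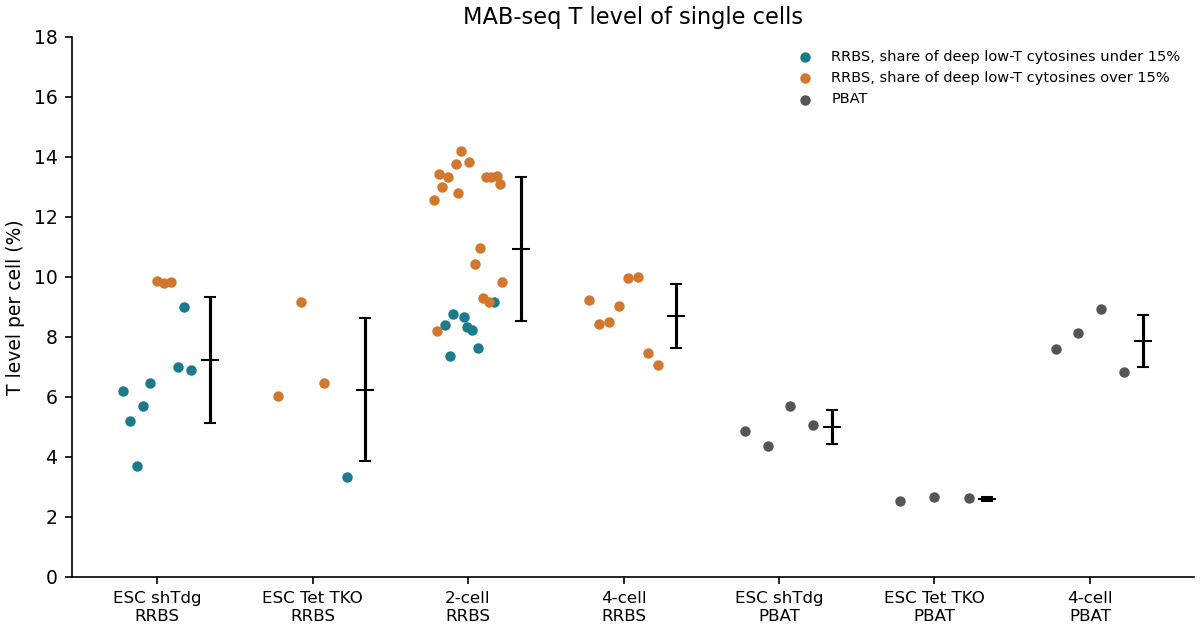
T level (percent of reads, mean over CpG cytosines) of each single cell by group, coloured by the noise set of the RRBS cells. Bars are the mean and SD over cells, and the 4 shTdg PBAT cells (4.35% to 5.71%) lie above the 3 Tet TKO PBAT cells (2.52% to 2.64%), while the RRBS lines overlap.

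Pooled libraries showed where in the genome T accumulated in shTdg ESCs. Library levels were 6.59% ± 1.38 in shTdg and 2.87% ± 0.0814 in Tet TKO ESCs (SD, n = 2 each), with 6.12% in the regular shTdg library. Of 92309 windows tested, 5536 were higher in shTdg than in Tet TKO ESCs and 24 were lower. The higher windows held 11.6% T ± 1.99 in shTdg and 1.17% ± 0.211 in Tet TKO libraries, values from the libraries that selected them. By CpG number, the higher windows were 11% of the windows with 20 to 59 CpGs, 4.82% of those with under 20 and 0.847% of those with 60 or more. In that last class the mean level was 2.89% ± 0.756 in shTdg and 1.90% ± 0.00606 in Tet TKO libraries, against 5.95% ± 1.29 and 1.88% ± 0.0343 with 20 to 59 CpGs and 5.59% ± 1.60 and 1.82% ± 9.01e-05 with under 20, so the levels with under 20 and with 20 to 59 CpGs lay closer than the shares of higher windows. Autosomes had 4.89% to 7.89% of their windows higher and the X chromosome 3.79%. The mean difference over tested windows was 3.48 points on the X chromosome and 3.49 to 3.88 points on single autosomes, so the means differed less than the shares.

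These calls came from edgeR's quasi-likelihood test. With edgeR's negative binomial dispersion 1749 windows were higher and 1 lower, and with Fisher's exact test on summed reads 21948 and 433. Each library bore on the count, which was 336 higher windows without Tet TKO replicate 2, 1852 without shTdg replicate 2 and 2838 without Tet TKO replicate 1. The lower windows numbered 4, 6 and 3 without shTdg replicate 1, shTdg replicate 2 and Tet TKO replicate 2, and 13 with the replicate number as a block.

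Among the 5 higher windows with the lowest p, the 1 on chromosome 8 from 56205001 to 56206000 rose from 1.59% ± 0.166 in Tet TKO to 10.1% ± 2.11 in shTdg ESCs (edgeR adjusted p = 3.11e-25). It held 3305 to 7604 reads per library on only 5 to 7 cytosines, while these libraries had a median of 3 to 6 reads per cytosine. Its low p thus reflects unusual depth as well as the difference, and the source of that depth was not tested. The window on chromosome 17 from 71909001 to 71910000 stood at 74.1% ± 1.78 in shTdg against 0% in Tet TKO, with 113 and 180 reads in the Tet TKO libraries. Those on chromosome 9 (3006001 to 3007000), chromosome 11 (66524001 to 66525000) and chromosome 6 (20079001 to 20080000) stood at 26.5%, 23.9% and 28.7% in shTdg against 3.65%, 3.08% and 4.19%. In each of these 3 windows 1 cytosine held up to 93.7%, 86.9% and 89.4% of the T reads of a library. Without cytosines at 80% T or more, only the chromosome 8 window of the 5 still passed (adjusted p = 3.97e-25), and the difference on chromosome 9 was −0.759 points. The count over all windows then stood at 5214 higher and 14 lower. Of the 5 named lower windows, those on chromosome 3 (113569001 to 113570000), chromosome 7 (16434001 to 16435000) and chromosome 9 (3029001 to 3030000) still passed, with differences of −17.4, −16.1 and −6.30 points.

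Dnmt TKO ESCs, of the line J1, lack the DNA methyltransferases and so have no 5-methylcytosine for TET enzymes to oxidise, which makes them another background beside Tet TKO cells of the line E14. Their library level was 3.5% ± 0.22 (SD, n = 2) against 2.87% ± 0.0814. Of 70185 windows tested, 218 were higher and 36 lower in Dnmt TKO. The higher windows held 24.2% T ± 1.27 against 1.63% ± 0.140, values from the libraries that selected them. They were 0.288%, 0.381% and 0.275% of the windows with under 20, 20 to 59 and 60 or more CpGs. The window on chromosome 7 from 97058001 to 97059000 stood at 46.9% ± 7.26 against 1.46% ± 0.345 (edgeR adjusted p = 4.29e-47). Those on chromosome 9 from 3006001, chromosome 17 from 71909001 and chromosome 6 from 20079001 were again among the 5 with the lowest p, at 27.6%, 75.1% and 28.0%. Of 66882 windows tested in both ESC comparisons, 216 were higher in Dnmt TKO, and 174 of these were also higher in shTdg, against 17.2 by independent lists. Both comparisons use the same Tet TKO libraries, which by itself favours shared calls. Dnmt TKO cells have no 5-methylcytosine to oxidise, so T at these shared windows need not mark 5fC or 5caC in shTdg ESCs. Cytosines at 80% T or more numbered 3148 of 619390 in Dnmt TKO and 1300 of 717513 in Tet TKO ESCs. Without them 25 windows were higher and 21 lower, and of the 5 named higher windows that on chromosome 17 was no longer tested and the other 4 did not pass, while 4 of the 5 named lower ones did. Counts by edgeR's negative binomial dispersion were 20 higher and 0 lower (577 windows at an unadjusted p under 0.05, against 1239 in the quasi-likelihood test), and by Fisher's exact test 2096 and 602. Without Dnmt TKO replicate 1 the counts were 137 and 9, and without Tet TKO replicate 2 they were 81 and 11.

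In the zygote the paternal genome was compared with sperm. Library levels of T were 11.4% ± 0.0435 in paternal pronuclei and 4.71% ± 0.628 in sperm (SD, n = 2 each), while the BS level was 55.7% ± 3.05 in pronuclei and 69.1% ± 0.958 in sperm. At the 46393 windows with a sperm BS level over 80%, T rose from 2.94% ± 0.0143 in sperm to 12.3% ± 0.492 in pronuclei and the BS level fell from 94.6% ± 1.24 to 73.7% ± 4.30. At the 7215 windows between 20 and 80% the T levels were 3.69% ± 0.00405 and 8.73% ± 0.0836, and the BS levels 55.1% ± 0.347 and 48.5% ± 1.41. At the 11695 windows under 20% they were 3.65% ± 0.0124 and 3.28% ± 0.299 for T, and 3.21% ± 0.0915 and 7.17% ± 0.425 for BS. The classes were set on the same sperm BS libraries. Sperm libraries are titled regular and pronuclear ones low-input in both assays, so differences between the tissues cannot be separated from those between the preparations.

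**Figure D2:**
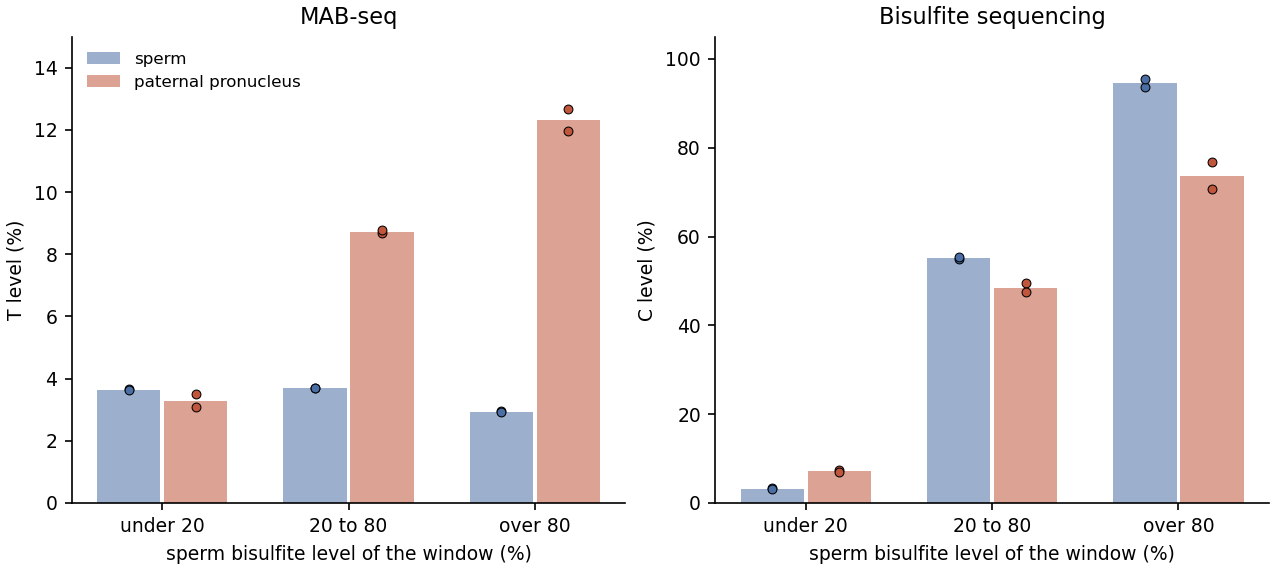
T level in MAB-seq and C level in bisulfite sequencing (percent) of sperm and paternal pronuclei, by the sperm bisulfite level of 1-kb windows. Bars are means of 2 libraries and points the libraries, and in windows over 80% T stood at 2.94% in sperm and 12.3% in pronuclei.

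Window by window, 16249 of 77541 windows were higher in T in pronuclei than in sperm and 135 were lower. The higher windows stood at 23.1% ± 3.23 in pronuclei and 2.33% ± 0.0218 in sperm, values from the libraries that selected them. They were 23.7%, 15.1% and 0.242% of the windows with under 20, 20 to 59 and 60 or more CpGs. Of the lower windows, 50 had 60 or more CpGs, and 113 of the 127 with a sperm BS level had one under 20%. On the X chromosome 10.01% of windows were higher, against 19.3% to 24.6% on single autosomes. The mean difference over tested windows was 4.71 points on the X chromosome and 6.83 to 8.37 points on single autosomes, so the means differed less than the shares. Named higher windows included chromosome 18 from 70920001 to 70921000 (56.5% ± 14.4 in pronuclei, 2.37% ± 1.98 in sperm, adjusted p = 2.58e-21), chromosome 10 from 90331001 to 90332000 (35.6% ± 4.15 and 1.54% ± 0.857), and chromosome 11 from 3073001 to 3074000 (11.9% ± 1.13 and 3.45% ± 0.439). The chromosome 11 window held 13763 to 20556 reads on 15 to 18 cytosines, against library medians of 7 to 12 reads per cytosine. The windows on chromosome 15 from 78925001 and chromosome 6 from 112791001 stood at 50.7% ± 34.9 and 39.5% ± 24.4 in pronuclei. The pronuclear libraries thus differed there. Named lower windows on chromosome X (102143001 to 102144000), chromosome 12 (110031001 to 110032000) and chromosome 6 (48036001 to 48037000) rested on sperm replicate 1, without which their differences were 1.53, 0.164 and 0.758 points. With edgeR's negative binomial dispersion 4950 windows were higher and 46 lower, and with Fisher's exact test 34665 and 1562. Without sperm replicate 1 the counts were 3316 and 59, without sperm replicate 2 they were 3664 and 68, and without pronuclear replicate 1 the lower windows numbered 322.

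In BS-seq 23737 of 77426 windows were lower in pronuclei than in sperm and 1727 were higher. The lower windows fell from 93.6% ± 1.40 to 57.9% ± 5.72, and they made up 34.8% of windows with under 20 CpGs and 0.0336% of those with 60 or more. The higher windows made up 9.06% of windows with 60 or more CpGs, and in that class they rose from 1.06% ± 0.0771 to 26.2% ± 2.34. These values, like those of the lower windows, come from the libraries that selected them. Over all 2715 windows with 60 or more CpGs covered in every pronuclear and sperm library, BS was 1.05% ± 0.00326 in sperm and 4.39% ± 0.482 in pronuclei. The window on chromosome 8 from 56205001 to 56206000 had the lowest p of the lower windows, at 78.2% ± 0.468 in sperm and 25.0% ± 1.82 in pronuclei (edgeR adjusted p = 1.66e-19), and that on chromosome 11 from 3073001 to 3074000 was among the 5 named ones, at 42.7% ± 0.223 and 30.05% ± 0.0155. The chromosome 8 window held 5311 to 7336 reads on 6 cytosines and the chromosome 11 window 12152 to 30413 reads on 16 to 23. Library medians were 10 to 13 reads per cytosine, so their low p reflects unusual depth as well as the difference. Windows on chromosome 15 (99887001 to 99888000) and chromosome 19 (10751001 to 10752000) fell from 94.6% ± 0.506 to 24.1% ± 0.525 and from 97.6% ± 1.14 to 34.5% ± 2.75. Higher windows included chromosome 9 from 79667001 to 79668000 (0.658% ± 0.335 in sperm, 69.3% ± 1.39 in pronuclei) and chromosome 10 from 115550001 to 115551000 (1.38% ± 0.139 and 49.0% ± 3.23). edgeR's negative binomial dispersion called 0 windows in either direction, with 21811 at an unadjusted p under 0.05 (32289 in the quasi-likelihood test), and Fisher's exact test 41468 lower and 3983 higher. Without sperm replicate 1 the counts were 10689 lower and 953 higher, and without sperm replicate 2 they were 4759 and 726.

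Over all windows, most of those that gained T were also lower in BS. Among the classes by sperm level this majority was seen only over 80%. Between 20 and 80% the overlap still exceeded that of independent lists, 392 windows against 139, as it did over 80%, 10419 against 6008. Windows under 20% averaged 3.21% BS in sperm, so few could lose the 10 points that a call needs. The modified bases that MAB-seq reads as T do not read as C in BS-seq, so a T gain may itself entail some BS loss. Of 65303 windows tested in both assays, 14625 were higher in T, and 10813 of these (73.9%) were lower in BS, against 21.3% of the other windows and 4834 by independent lists. Within windows over 80% in sperm the shares were 76.6% and 30.7%, between 20 and 80% they were 40.7% (of 964 windows higher in T) and 10.3%, and under 20% they were 3.7% (of 54) and 0.524%. Across windows the T gain and the BS loss correlated at Pearson's r = 0.547 and Spearman's rho = 0.584, and windows are not independent replicates.

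Windows called in pooled libraries were then read in single cells, which had no part in the calls. At windows higher in pronuclei than in sperm, 2-cell blastomeres held 13.5% T ± 1.61 (SD, n = 26 cells) against 5.96% ± 0.937 at tested windows that were not called, and the difference lay between 5.02 and 10.2 points in the 26 blastomeres. In 4-cell blastomeres the levels were 11.3% ± 1.10 against 5.85% ± 0.510 by RRBS (n = 8) and 10.9% ± 1.46 against 5.55% ± 0.536 by PBAT (n = 4). Tet TKO ESCs stood at 3.33% ± 1.09 against 3.46% ± 0.923 (n = 4). At windows higher in shTdg than in Tet TKO pools, single shTdg ESCs held 8.90% ± 2.82 against 5.10% ± 1.68 by RRBS (n = 11) and 7.11% ± 0.981 against 4.52% ± 0.454 by PBAT (n = 4). Single Tet TKO ESCs held 3.41% ± 0.850 against 3.40% ± 0.997 there (n = 4). The difference lay between 0.429 and 5.61 points in the 11 shTdg RRBS cells and between −0.399 and 0.705 points in the 4 Tet TKO cells. Replicate 4 of the shTdg cells had the lowest and lay within the Tet TKO range. Its level with at least 5 reads per cytosine, 2.35%, also lay under that of the lowest Tet TKO cell (2.44%). RRBS cells were read at cytosines with at least 5 reads.

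**Figure D3:**
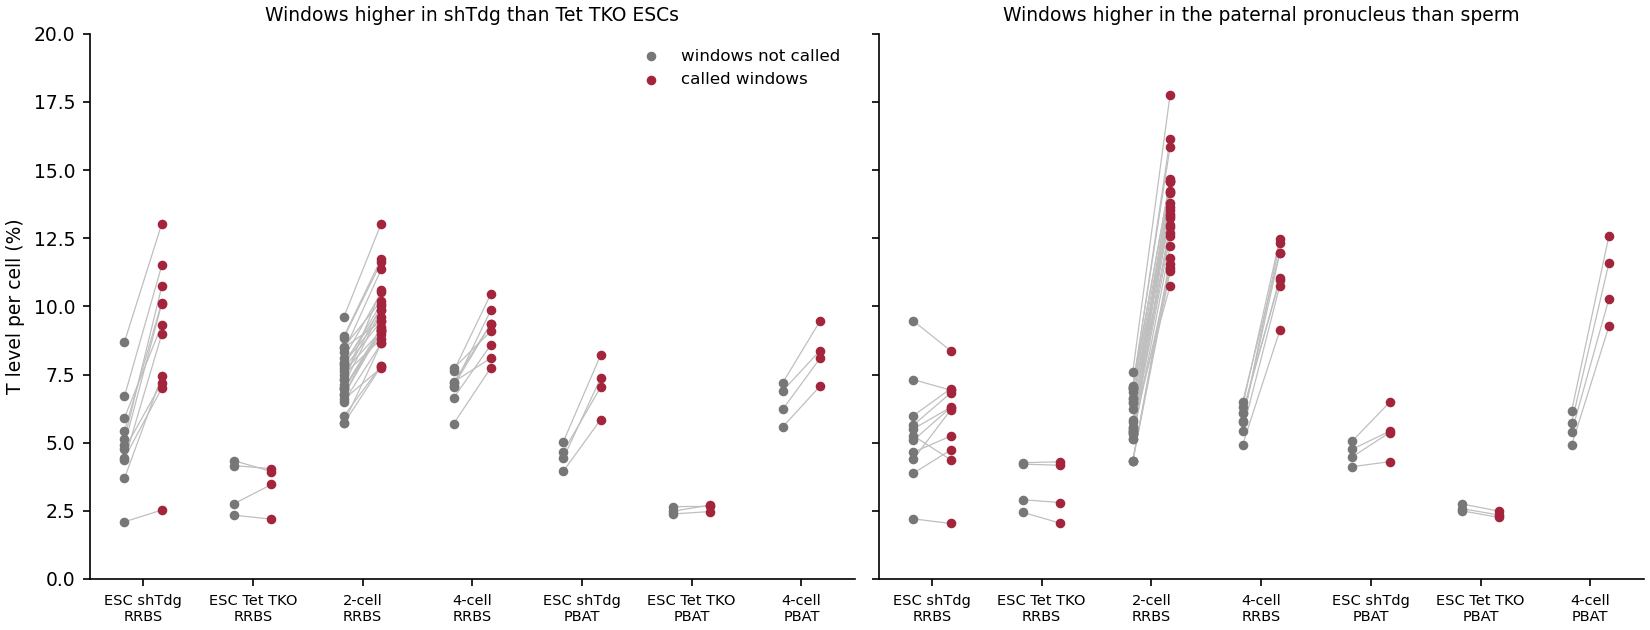
T level (percent) of each single cell at windows called higher in pooled libraries and at tested windows not called, for the ESC comparison and the zygote comparison. Lines join the values of 1 cell, and at the windows higher in pronuclei the 26 2-cell blastomeres rose by 5.02 to 10.2 points.

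The next question was on which DNA strand of each chromosome the T lay. In 2-cell blastomeres the T-positive cytosines were concentrated on 1 strand of a chromosome, with a strand bias of 0.275 ± 0.0885 (SD, n = 18 embryos) and an index beyond 0.3 at 34.6% of 494 chromosomes, 87 towards the plus and 84 towards the minus strand. Over the autosomes of a blastomere 13.5% ± 2.28 of cytosines were T-positive on the strand with more and 8.21% ± 2.45 on the other (SD, n = 26 cells). The bias was 0.0729 ± 0.0471 in single shTdg ESCs (n = 11 cells) and 0.0140 ± 0.00963 in Tet TKO ESCs (n = 4 cells) by RRBS, and 0.202 ± 0.0559 (n = 4 cells) and 0.0167 ± 0.00603 (n = 3 cells) by PBAT. The range over 2-cell blastomeres (0.145 to 0.438) overlapped that over shTdg RRBS cells (0.00896 to 0.172), and shTdg RRBS cells overlapped Tet TKO cells (0 to 0.0212). With at least 5 reads per cytosine the lowest 2-cell blastomere (0.320) lay above the highest shTdg RRBS cell (0.226), as it did on pooled T reads (0.285 and 0.225) and with at least 3 reads (0.263 and 0.215). Within low-noise cells the bias was 0.356 ± 0.0638 in 7 2-cell embryos and 0.0817 ± 0.0497 in 8 shTdg cells, and within high-noise cells 0.224 ± 0.0593 in 11 embryos and 0.0497 ± 0.0366 in 3 shTdg cells.

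The 2 4-cell embryos measured by RRBS had a bias of 0.355 ± 0.0286, and 52.6% of their 152 chromosomes lay beyond 0.3 while 37.5% lay under 0.15. The difference of −0.0799 between 2-cell and 4-cell embryos did not pass an exact permutation test (p = 0.253, n = 18 and 2 embryos, smallest possible p 0.0105). Among high-noise cells it was −0.131 (exact permutation p = 0.0256, n = 11 and 2 embryos, the smallest possible), and on pooled T reads 0.00175.

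Sister blastomeres of a 2-cell embryo carried T on opposite strands. Over the 19 autosomes the indices of the cells a and b of 1 embryo correlated at a mean Pearson's r of −0.974 ± 0.0102 (SD, n = 8 embryos, −0.990 to −0.961), with opposite signs at 17 to 19 of the 19 chromosomes. Cells a and b of different embryos gave a mean of −0.0605 over 56 combinations, from −0.567 to 0.346. The exact test over all 40320 re-pairings gave p = 4.96e-05, the smallest possible.

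**Figure D4:**
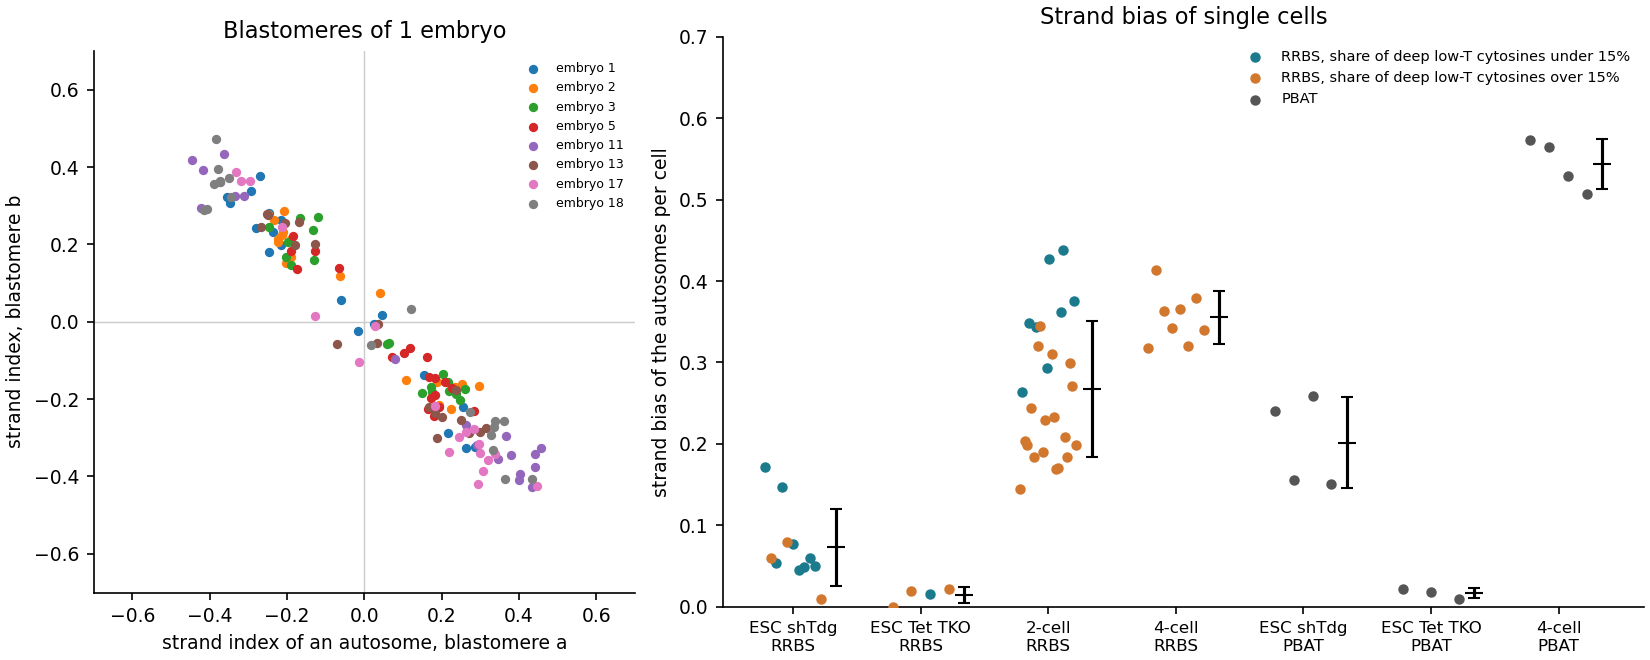
Strand index of each autosome in blastomere a against blastomere b for the 8 2-cell embryos with both cells, and the strand bias of each single cell by group with the mean and SD over cells. Sister blastomeres lie along a falling diagonal (mean r −0.974), and Tet TKO cells lie between 0 and 0.0220.

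Some chromosomes changed strand part of the way along, the mark by which the study maps sister chromatid exchange. In 2-cell blastomeres 57 such switches were found, 2.19 ± 1.90 per cell (SD, n = 26 cells, 0 to 7), and 20 of the 26 cells had at least 1. Low-noise cells had 2.88 ± 2.10 (n = 8) and high-noise cells 1.89 ± 1.78 (n = 18). RRBS blastomeres of 4-cell embryos had 3 in 8 cells. A switch needs bias to opposite strands on its sides, and 37.5% of their chromosomes had an index under 0.15. Recovery was not simulated for 4-cell or PBAT cells, so these counts do not tell whether switches differ between the stages. No switch was found in the 11 shTdg and 4 Tet TKO RRBS ESCs. In simulations at the strand indices of these cells 2 of 209 true switches were recovered in shTdg and 0 of 76 in Tet TKO cells, so the absence of calls says little about ESCs. By PBAT there were 14 in 4 4-cell blastomeres, 6 in 4 shTdg ESCs and 2 in 1 of 3 Tet TKO ESCs, the last being the background in cells without TET enzymes.

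Switches of sister blastomeres often lay near one another. In the 8 embryos with both cells, 22 of 37 switches (59.5%) had a switch in the sister within 5 Mb, against 8.78% on average over all re-pairings (exact permutation p = 5.95e-04, n = 8 embryos). The share was 37.8% within 2 Mb (p = 0.0107) and 86.5% within 10 Mb (p = 9.92e-05) in the same exact test. The 11 matched pairs ran in opposite directions, which the opposite strands of sister cells already entail, with a median distance of 1 Mb, and 6 lay within 1 Mb. Examples are embryo 1 on chromosome 2, at 145 Mb in one cell and 144 Mb in the other, and on chromosome 4, at 117 and 116 Mb. With matches taken as 1 event, the 18 embryos held 46 events, 7 on chromosome 5, 6 each on chromosomes 2 and 9, and 0 on chromosomes 16, 17 and 19. This order depends on the limit of 5 Mb, since with matches within 10 Mb there were 41 events, 6 on chromosome 2 and 5 each on chromosomes 5 and 9. Events per chromosome rose with its covered length over the 19 autosomes (Pearson's r = 0.547, permutation p = 0.0172, Spearman's rho = 0.675, p = 0.00214, r = 0.629 without the 2 chromosomes farthest from the median length), and within 10 Mb r was 0.594 and rho 0.688. Covered length was the only property of chromosomes that events were related to. This relation was not among the tests fixed beforehand. A switch needs 5 Mb on each side and a minimum gain in likelihood, which shorter chromosomes may meet less often, and this was not corrected for.

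**Figure D5:**
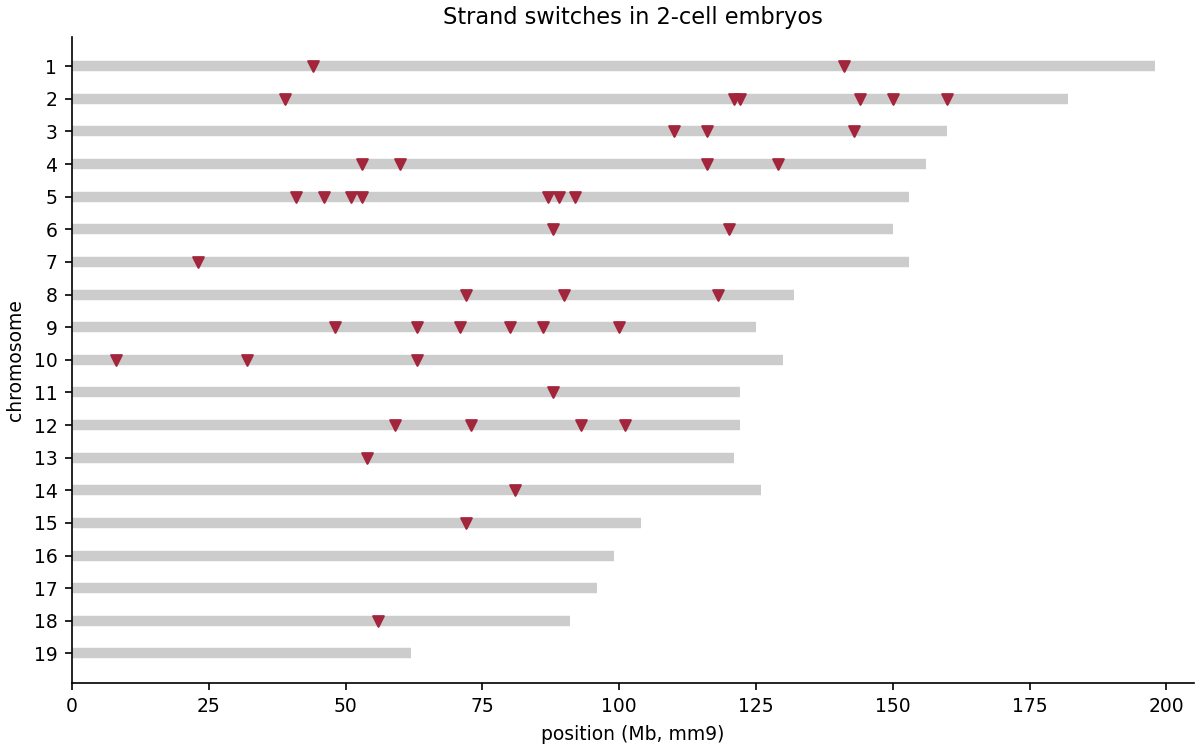
Positions (Mb, mm9) of the 46 strand switch events of the 18 2-cell embryos on the autosomes, with bars as long as the covered part of each chromosome. Triangles are events, 7 of them on chromosome 5 and 0 on chromosomes 16, 17 and 19.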

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

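The tests of the X chromosome and of recurring places of strand switches were chosen only after the results were seen, while the re-pairing test of switches had been fixed earlier. Over 20 groups of 4 to 10 samples tested for a sample far from the others, 1 stood out, and chance gives about 1 in 20. Among the single shTdg ESCs read by PBAT, replicate 17 had 0 strand switches and the other 3 cells had 2 each. The 4 blastomeres of the 4-cell embryo read by PBAT entered no comparison of strand bias between groups, and their strand bias averaged 0.544, above the 0.0101 to 0.0220 of Tet TKO PBAT cells. The X chromosome was outside the measure of strand bias, and its absolute strand index averaged 0.309 over the 11 2-cell blastomeres with an X coverage over 3.5% of the autosomal cytosines, above the 0.0203 to 0.143 of Tet TKO RRBS cells.

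The X chromosome was biased in some 2-cell embryos and hardly in others. Samples fell apart by X coverage, 9 embryos at 2.36% to 2.94% of the autosomal cytosines (1 X dose) and 9 at 4.35% to 4.91% (2 X doses), and the absolute X index was 0.0979 ± 0.0901 in the first and 0.311 ± 0.134 in the others (SD, exact permutation p = 0.00107). A weaker strand bias on every chromosome with 1 X dose was argued against, since at 5 or more reads per cytosine the autosomal bias was 0.455 ± 0.0560 and 0.421 ± 0.0718 over the embryos, and its lowest value with 1 X dose, 0.381, lay above the 0.167 that the X would call for. A candidate explanation is that the strand-biased sites lie on paternally inherited chromosomes, since a male embryo has its X from the mother. It stays a hypothesis, because the parent of each X was not read from these data and X doses were judged from coverage alone. Covered Y cytosines numbered 4 to 57 with 1 X dose and 0 to 6 with 2. The ranges overlapped only through blastomere 3b, with 4 against 11 in its sister 3a, so Y coverage otherwise went with the X doses.

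Strand switches in 2-cell blastomeres were weighed against technical sources. Counting noise within single cells is argued against by their return in the sister cell (exact permutation p = 5.95e-04 over the re-pairings). Inverted or misplaced segments of the reference would put switches at one place in many embryos, and at most 2 of the 18 embryos had one within 2 Mb of any place. Exchange between sister chromatids may account for the switches, since it would leave one at the same place in both sister cells, and it stays a hypothesis. The 2 switches in 1 of the 3 Tet TKO PBAT cells show that the method also places some in cells without TET enzymes.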

How the results depend on the processing

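The alternatives with noise sets, 5 reads per cytosine in strand measures, the negative binomial dispersion and the exclusion of cytosines at 80% T or more were chosen after the data were seen, as were those for library levels. Of the alternatives to the comparisons, 128 kept their direction and their side of the threshold or stayed within the spread or within 1.5 times the count, 43 moved further, 1 newly passed its threshold and 1 reversed. In the others the cause was not tested. With at least 5 reads per cytosine the PBAT ESC difference was 2.97 points in place of 2.40 and the strand bias difference between 2-cell embryos and shTdg ESCs 0.333 in place of 0.202, and the latter was 0.292 on pooled T reads. The strand bias difference between 2-cell and 4-cell embryos was 0.00175 on pooled T reads and −0.131 among high-noise cells.

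The windows higher in shTdg (5536) and lower (24) numbered 21948 and 433 with Fisher's exact test and 1749 and 1 with the negative binomial dispersion, and leaving out 1 library gave 336 (Tet TKO replicate 2) to 4466 and 3 to 26. Without cytosines at 80% T or more, 14 were lower. Windows higher (218) and lower (36) in Dnmt TKO numbered 2096 and 602, then 20 and 0, and 81 (Tet TKO replicate 2) to 190 and 9 (Dnmt TKO replicate 1) to 26 on leaving out 1 library, with 25 and 21 without those cytosines. The 0 by edgeR's negative binomial dispersion stands beside 577 windows at an unadjusted p under 0.05. Windows higher (16249) and lower (135) in pronuclear T numbered 34665 and 1562, then 4950 and 46, and 3316 (sperm replicate 1) to 19051 and 59 to 322 (pronuclear replicate 1), with 206 lower without a minimum difference. Windows lower (23737) and higher (1727) in pronuclear BS numbered 41468 and 3983 with Fisher's exact test, 0 and 0 with edgeR's negative binomial dispersion (21811 at an unadjusted p under 0.05), and 4759 (sperm replicate 2) to 32176 and 726 to 2585 on leaving out 1 library. Where this left 1 library in a group, that library was assumed to vary like the others.

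Without 1 Tet TKO cell, the single ESC difference by RRBS ranged from 0.0224 to 1.97 points, the 2-cell to Tet TKO difference from 3.52 to 5.47 points, and the strand bias difference of shTdg and Tet TKO cells from 0.0542 to 0.0613. The last difference, 0.0589 in all cells, was 0.0998 with at least 5 reads per cytosine and 0.0362 among high-noise cells. Without 1 cell of either line the PBAT difference ranged from 2.16 to 2.61 points, and without 1 4-cell embryo the 2-cell to 4-cell differences ranged from 1.18 to 2.88 points and, in strand bias, from −0.100 to −0.0596. With the replicate number as a block, 13 windows were lower in shTdg, and no other count moved by over 1.5 times. Same-numbered libraries did not deviate together (correlations of −0.00441 to −9.49e-05, single ESCs −0.0473), and the blocked difference of 4 pairs of single ESCs was 2.05 points. Of 418 alternatives for named windows, 369 still passed, 43 did not and 6 reversed. These were, without cytosines at 80% T or more, shTdg chromosome 9 from 3006001 (−0.759 points), Dnmt TKO chromosome 6 from 20079001 (−0.110) and chromosome 16 from 48547001 (0.448), where the left-out cytosines held the difference, and pronuclear T on chromosome X from 102143001, chromosome 12 from 110031001 and chromosome 6 from 48036001, with −29.9, −40.6 and −42.6 points without sperm replicate 2 and 1.53, 0.164 and 0.758 without replicate 1.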

Other observations

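The tests of how biased strands are shared among 4-cell blastomeres were chosen only after the strand indices had been seen. Pooled 2-cell embryos, a single library of about 50 embryos by its label, kept the order of the zygote by sperm BS level. Their T level was 5.31% at the 52542 windows over 80% in sperm, 4.28% at 7954 windows between 20 and 80% and 2.57% at 12190 windows under 20%. Paternal pronuclei held 12.5%, 8.89% and 3.30% there. The embryos hold both parental genomes and the pronuclei only the paternal one, so these levels do not measure a change between the stages. At windows higher in pronuclei than in sperm the pooled embryos held 7.31% against 3.61% at windows not called, and at windows higher in shTdg ESCs 5.42% against 4.39%. The ESC and zygote lists of T-rich windows, which share no library, had 2098 windows in common among 67423 tested in both, against 1128 by independent lists. Away from RRBS windows the PBAT pools held 4.65% T in shTdg (Wilson 95% interval 4.64% to 4.66%) and 2.41% in Tet TKO ESCs (2.39% to 2.43%), and at windows with 60 or more CpGs 3.51% (3.5% to 3.53%) and 2.01% (1.98% to 2.05%).

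In 4-cell embryos a chromosome often had 1 blastomere biased to the plus strand, 1 to the minus strand and 2 with an index within 0.25 of 0. In the 2 RRBS embryos this was so for 28 of 38 chromosomes, against 7.39 on average and at most 18 when chromosomes were shuffled within each cell (permutation p = 1e-04, the smallest that 10000 shuffles give), as may be so if each biased strand goes to a single cell of the 4. In the PBAT embryo it was so for 8 of 19, against 2.51 on average (permutation p = 6.0e-04), but 11 of the 19 had over 2 biased cells, so the same hypothesis stays open there, and over 2 biased cells were also seen at 6 and 4 chromosomes of the RRBS embryos 1 and 3. A second hypothesis, that plus and minus carriers come from different cells of the 2-cell stage, asks for a pairing of the 4 cells with few opposite carriers within pairs, and embryo 1 had 1 with a paired to b and c to d, against 4.94 on average for the lowest shuffled pairing (permutation p = 0.00480). Embryos 3 and 2 gave permutation p of 0.224 and 0.396, and the labels do not say which cells are sisters, so this cannot be told apart from chance there.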
